A study of Mus musculus with 12 samples.

How the data were processed

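Polyadenylated RNA from the ventral part of the right hippocampus of 12 mice was sequenced as 1 library per mouse. The labels place 3 mice in each of 4 groups: wild-type (WT) females, WT males, Angelman syndrome (AS) females and AS males. The mice were 12 to 16 weeks old. All libraries carry the same lane number, 7, and the labels give no other batch. The mutation carried by the AS mice is not stated in the labels.

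The submitters' notes name Trimmomatic, Bowtie2 and RSEM with the GRCm38 (mm10) mouse genome and give no versions. The deposited table holds 13951 Ensembl gene identifiers in 12 columns, read here as the natural log (ln) of an RSEM abundance plus 1. Its values run from 0.100 to 10.08 with no zeros and no whole numbers, so it does not hold counts. Whether the abundance is TPM or FPKM is not stated, nor are the log base, the added constant, the normalization and the filter. Of the values between 2 and 5 in the first library, 100% occur in all 12 columns, against 95.8% between 1 and 2, 9.46% between 0 and 1 and 16.1% between 5 and 6. Above 6 none do. The table was therefore read as quantile-normalized over the middle of its range. Back-transformed with base e, the values of a library add up to 547558 to 587587. With base 2 the totals are 121858 to 124206, and with base 10 they exceed 1.32e+10. Base 10 was set aside and base 2 cannot be ruled out. The tests rest on differences of the logs, so for the same genes tested their p does not depend on the base. At base 2 each log2 difference would be 0.693 times as large as printed. The filter on mean abundance does depend on the base, so other genes could be left out, and no fit was run with base 2. The deposited values give no read counts, so the depth of each library and the counting error behind each value are unknown, and no counting intervals are given.

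Values were converted to log2(abundance + 1) by dividing by the natural log of 2. Genes with a mean abundance under 1 were left out (93 genes), which left 13858 tested. Symbols, coordinates and biotypes came from the mouse annotation on GRCm38, in which 13735 identifiers had a symbol and 216 had none. One linear model with the 4 group means was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend with mean expression. Residual degrees of freedom were 8. The 6 contrasts were AS minus WT in females, AS minus WT in males, the mean of these differences, their difference (the interaction of genotype and sex, male minus female), and male minus female in WT and in AS. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Errors on log2 differences are standard errors of the model, and intervals are at 95%. No covariate was used, because replicate numbers follow accession order and pair nothing.

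Of 43 gene lists, 42 had at least 3 tested members. They cover cell types of the hippocampus and of tissue that a dissected piece can hold, neighbouring regions, neuronal functions, stress and metabolism, sensory systems, sex chromosomes and the locus of Ube3a. Each list was tested with camera in limma with a preset correlation between genes of 0.01, adjusted over the lists within a contrast. Beside it stand camera with the correlation estimated from the data and fry, a rotation test of whether the genes of a list move one way on balance. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. List means per library were also compared by exact two-sided permutation, of genotype within each sex or of sex over all libraries, a test added after the data were seen. The smallest p that 3 libraries against 3 allow is 0.1.

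The genes named in each comparison follow a rule. Up to 15 called genes per direction with the smallest p are named if the libraries of the groups compared do not overlap. Where fewer than 5 genes pass in a direction, the 5 with the smallest unadjusted p are named as not having passed. Y-linked genes and Xist are named under their own lists. The rule was written for normalized counts, and non-overlap was judged on log2 values instead. Up to 4 members are named per list that passed. Restricting these to members with an unadjusted p under 0.05 was added after the data were seen. Genes with predicted-gene or pseudogene names are summarised. The groups, contrasts, other tests, lists, naming rule and most of the alternatives below were chosen before the data were examined. The plan assumed that the table might hold counts and had set this limma model for the case of normalized values.

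Alternatives tried were another added constant, no filter and a stricter filter, fits of only the groups compared, each of the 12 libraries left out in turn, and the estimated correlation and fry for lists. Chosen after seeing the data were library quality weights, a robust prior for the variance, quantile normalization applied again, the choroid plexus list mean as a covariate, and a fit without the 4 libraries highest in choroid plexus genes. Alternatives that need counts were not run. Other splits of the libraries into groups of the same sizes were fitted in the same way. The 10 splits of 6 libraries were used for contrasts within a sex or genotype, and 100 relabellings drawn from the 200 of genotype within each sex for the other contrasts. The pipeline was tested on simulated data, drawn gene by gene from normal distributions with each gene's mean and spread, with a log2 change of 0.5, 1 or 2 added to 66 or 67 genes each. Simulated genes varied independently of each other, unlike the measured ones. At a change of 1 the model recovered between 83.6% and 95.5% of the changed genes, depending on the contrast. At a change of 0.5 it recovered 34.3% in females, 52.2% in males, 76.1% over both sexes and 19.4% for the interaction. The simulated fits called 135 to 185 genes, which eases the adjusted threshold, while fits of the measured data called 0 to 5. These shares can thus overstate what would be recovered in the measured data. The result of 1 gene is not reported here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.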

Results

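The data are 12 libraries of polyadenylated RNA from the mouse ventral hippocampus, 3 each from WT females, WT males, AS females and AS males. Angelman syndrome is a neurodevelopmental disorder caused by loss of the maternal copy of UBE3A, which encodes a ubiquitin ligase. The title of the series concerns sensory phenotypes that depend on sex, and the comparisons below ask which transcripts differ by genotype in each sex, over both sexes and between the sexes. Values are log2(abundance + 1) from the deposited normalized table, read as natural logs. If that table used base 2, each log2 difference below would be 0.693 times as large. The filter could then leave out other genes, and whether calls would change was not tested. The depth of the libraries is unknown. Across genes, pairs of libraries correlated with Pearson's r of 0.966 to 0.983, and genes are not independent replicates.

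Ube3a transcript levels differed between genotypes by less than their error. Ube3a (ENSMUSG00000025326, chromosome 7, 59228750 to 59311536, plus strand, GRCm38) averaged 0.12 lower on the log2 scale in AS females, a difference of -0.12 ± 0.13 (SE, 3 mice per group, limma). The difference was -0.05 ± 0.13 in males and -0.09 ± 0.09 over both sexes (adjusted p = 0.976), with a 95% interval of -0.29 to 0.12. That interval excludes a fall of more than 18.2% in the measured abundance + 1. The value covers the whole gene, the mutation is not given, and a transcript can remain where its protein is lost, so these levels do not check the genotype labels. The list of Ube3a and its imprinted neighbours, with 11 tested members, did not pass over both sexes (mean log2 difference -0.03, adjusted p = 0.404). Known protein substrates and partners of UBE3A did not pass either, with 8 members higher and 10 lower of 18 (adjusted p = 0.968).

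Sex-linked transcripts matched the sex labels in 11 of the 12 libraries. The 4 tested Y-linked genes (Eif2s3y, Ddx3y, Uty and Kdm5d) lay between 2.70 and 6.06 in the 6 male libraries. In the 6 female libraries they lay between 0.15 and 1.47, which is the level read as background, and 928 tested genes have a mean under 1.47. Xist (chromosome X, 103460366 to 103483254, minus strand), the RNA that silences an X chromosome, averaged 6.32 ± 0.18 (SD, n = 5) in the other female libraries and 0.29 ± 0.12 (SD, n = 6) in males. In WT female replicate 1 it was 0.35, at the male level, while the mean of the Y-linked genes was 0.68, at the female level. The X-inactivation and escape list has 7 tested genes besides Xist. In 4 of them males and the other females did not overlap, and these 4 (Kdm5c, Eif2s3x, Ddx3x and Kdm6a) were lower in this library than in every other female library, with Eif2s3x at 5.31 against 5.93 ± 0.08 (SD, n = 5) and Kdm6a at 3.03 against 3.41 ± 0.09 (SD, n = 5). Of all 7 genes 5 were, while Jpx at 2.15 and Ftx at 4.31 lay within the range of the other females.

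**Figure D1:**
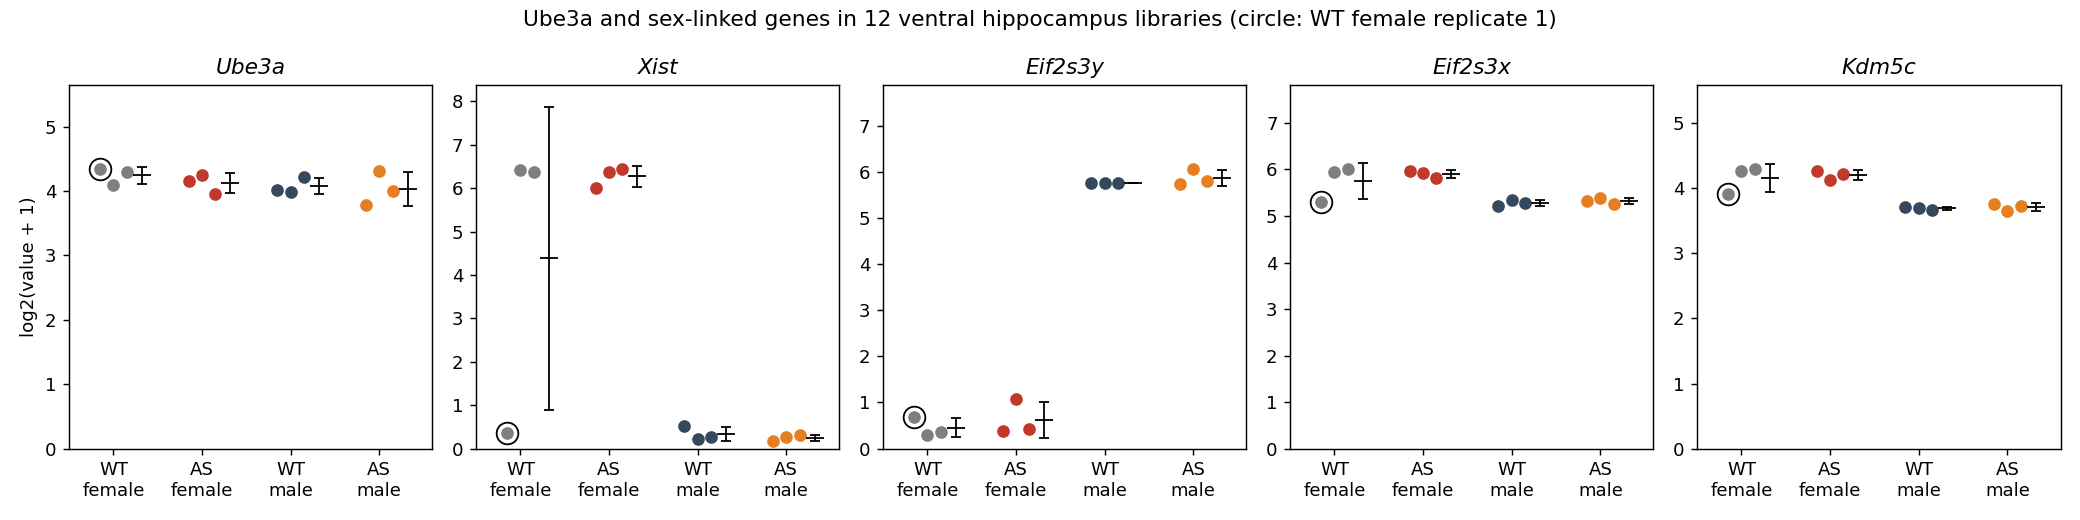
Levels of Ube3a, Xist, Eif2s3y, Eif2s3x and Kdm5c as log2(abundance + 1) in each of the 12 libraries (points), with the group mean and SD (bars, n = 3). WT female replicate 1 (circled) has Xist at 0.35, at the level of the males, and Eif2s3y at the level of the females.

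Choroid plexus transcripts varied widely between libraries of the same group. Ttr, which encodes the thyroid hormone carrier transthyretin (chromosome 18, 20665280 to 20674321, plus strand), ran from 2.33 to 11.7. The mean of the 26 choroid plexus genes was 4.91 in WT female replicate 2, 4.73 in AS female replicate 2, 4.05 in WT female replicate 1 and 2.92 in AS male replicate 2. In the remaining libraries it lay between 1.41 and 1.86. Group means were 3.61 ± 1.57 in WT females, 2.66 ± 1.79 in AS females, 1.55 ± 0.10 in WT males and 1.92 ± 0.87 in AS males (SD, n = 3). The first principal component held 20.6% of the variance, with Ttr and Folr1, which encodes a folate receptor, as its strongest genes.

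In females, the interneuron and chaperone lists passed as lower in AS mice, by camera with a preset correlation. Of 10 splits of the female libraries, 4 gave at least the real 10 lists (highest other 15), so chance cannot be excluded for their number. Of 18 interneuron genes 16 were lower, and the list mean was 4.63 ± 0.04 in AS against 4.82 ± 0.11 in WT females (SD, n = 3), lower than the WT mean in 3 of 3 AS libraries (adjusted p = 4.48e-06, and adjusted p = 0.455 with an estimated correlation). Its members with the smallest p were Dlx1, a transcription factor of interneuron development, at -0.29 ± 0.09, Reln, which encodes the secreted protein reelin, at -0.39 ± 0.15, the noncoding RNA Dlx6os1 at -0.34 ± 0.14, and Calb2, which encodes calretinin, at -0.55 ± 0.23. Of 21 heat shock and chaperone genes 19 were lower, by a mean log2 difference of -0.13 (adjusted p = 0.000221, and adjusted p = 0.455 with an estimated correlation). Calr, which encodes the endoplasmic reticulum chaperone calreticulin, was at -0.23 ± 0.10. Without the 4 libraries highest in choroid plexus genes the chaperone list did not pass (adjusted p = 0.318).

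Another 8 of 42 lists passed in females, and each lost its call without at least 1 library. All 26 choroid plexus genes were lower in AS females (mean -0.94, adjusted p = 4.58e-06, and adjusted p = 0.775 with an estimated correlation), a call that ended without WT female replicate 2 or AS female replicate 1 (up to 0.324) and without the 4 libraries highest in choroid plexus genes (0.0657). Cytosolic ribosomal protein genes were lower by a mean of -0.06, with 46 of 58 lower (adjusted p = 0.000221, and adjusted p = 0.775 with an estimated correlation). The call ended without WT female replicate 3 (0.0630). Meningeal fibroblast genes were lower, with 13 of 14 lower and a mean of -0.44 (adjusted p = 0.0106, and adjusted p = 0.775 with an estimated correlation). That call ended without WT female replicate 3 or AS female replicates 1 or 3 (up to 0.521) and with the choroid plexus mean as a covariate (0.117). Glucocorticoid-responsive genes were lower, with 15 of 18 lower and a mean of -0.16 (adjusted p = 0.0324, and adjusted p = 0.775 with an estimated correlation). This list lost its call without WT female replicates 1 or 3 or AS female replicates 2 or 3 (up to 0.434). Nuclear genes of oxidative phosphorylation were lower by a mean of -0.03, with 50 of 69 lower (adjusted p = 0.0114, and adjusted p = 0.819 with an estimated correlation). This call ended without WT female replicate 3 or AS female replicates 2 or 3 (up to 0.482). Myelin and oligodendrocyte genes were higher in 19 of 19 cases, by a mean of 0.20 (adjusted p = 0.00374, and adjusted p = 0.790 with an estimated correlation). Their call did not hold without WT female replicates 1 or 3 or AS female replicate 3 (up to 0.521). Interferon-stimulated genes were higher, with 12 of 14 higher and a mean of 0.36 (adjusted p = 0.00281, and adjusted p = 0.775 with an estimated correlation), but the group mean of AS females was 3.15 ± 0.86 (SD, n = 3). That call ended without AS female replicate 2 (0.192) and without the 4 libraries highest in choroid plexus genes (0.904). X-inactivation and escape genes were higher in 8 of 8 cases, by a mean of 0.36 (adjusted p = 0.0208, and adjusted p = 0.699 with an estimated correlation), and this ended without WT female replicate 1, the library low in Xist (0.905), without AS female replicates 1 or 2, or without the 4 libraries highest in choroid plexus genes (0.804). With library quality weights the glucocorticoid, interferon and oxidative phosphorylation calls ended too (0.158, 0.174 and 0.119), as did the interferon call with a mean abundance of at least 5 (0.171).

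No single gene passed for AS against WT in females with limma (0 higher, 0 lower), while 438 had an unadjusted p under 0.05, against 693 expected by chance. That count was 762 without AS female replicate 2, 739 with library quality weights and 927 without the 4 libraries highest in choroid plexus genes. Groups did not overlap for 9.01% of genes, against 10% by chance. The genes with the smallest p did not pass (adjusted p = 1.00 for each). On the higher side they were Tmsb15b2, which encodes a thymosin that binds actin monomers, at 0.67 ± 0.13, the DNA repair gene Xrcc6 at 0.41 ± 0.09, Sorl1, which encodes a sorting receptor for the amyloid precursor protein, at 0.27 ± 0.06, Get4 at 0.25 ± 0.05 and 1 antisense RNA. On the lower side they included Tmem185a at -0.34 ± 0.07, Tm7sf2, which encodes a sterol reductase, at -0.41 ± 0.09, the histone gene Hist3h2a at -0.63 ± 0.15 and 1 pseudogene. Tmsb15b2 and Hist3h2a belong to families of similar genes, so their values may hold reads of relatives. On leaving out 1 library, 1 small noncoding RNA passed in each of 3 cases: Snord15b without WT female replicate 1, Gm24409 without WT female replicate 3 and Gm24166 without AS female replicate 1.

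In males, the chaperone list passed as lower and the proteasome list as higher in AS mice, by camera with a preset correlation. All 10 splits of the male libraries gave at least the real 3 lists (highest other 14), so chance cannot be excluded for their number. Of 21 heat shock and chaperone genes 18 were lower, and the list mean was 5.76 ± 0.05 in AS against 5.96 ± 0.11 in WT males (SD, n = 3), lower than the WT mean in 3 of 3 AS libraries (adjusted p = 0.0002, and adjusted p = 0.731 with an estimated correlation). The members with the smallest p were Sdf2l1, an endoplasmic reticulum stress gene, at -0.76 ± 0.28, the inducible heat shock gene Hspa1b at -0.32 ± 0.12, the small heat shock gene Hspb1 at -0.60 ± 0.23 and the mitochondrial chaperonin gene Hspe1 at -0.19 ± 0.08. Of 31 ubiquitin-proteasome subunit genes 25 were higher, with a list mean of 6.37 ± 0.04 in AS against 6.30 ± 0.04 in WT males (SD, n = 3, adjusted p = 0.0002, and adjusted p = 0.731 with an estimated correlation). Psmd14 was at 0.19 ± 0.07, Psmd7 at 0.12 ± 0.05, Psmc1 at 0.14 ± 0.06 and Psmd1 at 0.15 ± 0.07. Glucocorticoid-responsive genes were lower in 15 of 18 cases, by a mean of -0.28 (adjusted p = 0.00664, and adjusted p = 0.761 with an estimated correlation), while Nr3c2, the mineralocorticoid receptor gene on that list, was at 0.35 ± 0.14. That call ended without WT male replicate 3 or AS male replicate 1 (up to 0.420).

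No single gene passed for AS against WT in males with limma (0 higher, 0 lower), while 890 had an unadjusted p under 0.05, against 693 expected by chance (617 without WT male replicate 2, 1087 with library quality weights). Of the 10 splits of the male libraries, 4 gave at least 890 such genes, and the splits other than the real one ran from 498 to 1524. Groups did not overlap for 11.2% of genes, against 10% by chance. The genes with the smallest p did not pass (adjusted p = 0.748 for each). On the higher side were Sh3gl3, which encodes an endophilin of endocytosis, at 0.46 ± 0.08, the transferrin receptor gene Tfrc at 0.34 ± 0.07, Hscb, which encodes a co-chaperone of iron-sulfur cluster assembly, at 0.48 ± 0.10, the myosin light chain gene Myl4 at 0.82 ± 0.19 and 1 intronic RNA. On the lower side were Lynx1, which encodes a modulator of nicotinic acetylcholine receptors, at -0.54 ± 0.09, Aifm3 at -0.42 ± 0.08, Ogdhl at -0.33 ± 0.06, and the transcriptional regulators Bcl11a at -0.31 ± 0.06 and Zmynd8 at -0.35 ± 0.08. Without WT male replicate 2 the small noncoding RNA Snora21 passed (-4.68, adjusted p = 0.00027).

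Over both sexes, the chaperone and interneuron lists passed as lower in AS mice and the proteasome list as slightly higher, by camera with a preset correlation. The chaperone list had 19 of 21 genes lower, a mean log2 difference of -0.16 and a median of -0.11 (adjusted p = 2.59e-07, and adjusted p = 0.308 with an estimated correlation). Calr was at -0.24 ± 0.07, Hspe1 at -0.17 ± 0.05, Pdia6, a protein disulfide isomerase gene, at -0.22 ± 0.08 and Hspb1 at -0.44 ± 0.16 (SE, 6 mice per genotype). The interneuron list had 16 of 18 genes lower, with a mean of -0.12 (adjusted p = 0.000124, and adjusted p = 0.659 with an estimated correlation). Reln was at -0.37 ± 0.11, Lamp5 at -0.50 ± 0.16, the neuropeptide gene Vip at -0.28 ± 0.09 and Dlx1 at -0.17 ± 0.07. Proteasome genes were higher in 22 of 31 cases by a mean of 0.04 (adjusted p = 0.00208, and adjusted p = 0.659 with an estimated correlation), with Psmc2 at 0.10 ± 0.04. Taken by sex, interneuron genes did not pass in males, with 12 of 18 lower and a mean of -0.051 against -0.19 in females (adjusted p = 0.266), and proteasome genes did not pass in females, with 17 of 31 higher and a mean of 0.0074 against 0.071 in males (adjusted p = 0.650). The interaction, described below, did not pass for interneuron genes (adjusted p = 0.0994). The mean of the proteasome list was 6.35 in WT females, 6.36 in AS females and 6.37 in AS males, against 6.30 in WT males. The calls for this list in males, over both sexes, for the interaction and between WT sexes thus share the low WT males. Glucocorticoid-responsive genes were lower in 16 of 18 cases by a mean of -0.22 (adjusted p = 0.000432, and adjusted p = 0.659 with an estimated correlation), with the metallothionein gene Mt2 at -0.41 ± 0.15 and the stress gene Ddit4 at -0.28 ± 0.12. These 4 lists passed whichever library was left out, and with the choroid plexus mean as a covariate. Those fits used the same preset correlation, with which 89 of 100 relabellings of genotype gave at least 6 lists. With an estimated correlation, and with fry, 0 lists passed over both sexes. Exact permutation of the list means gave adjusted p from 0.525 to 0.77 for these 4 lists. None of their members passed over all genes tested, and 0 passed adjusted over the list alone, with 7 chaperone, 5 interneuron, 3 proteasome and 2 glucocorticoid-responsive genes at an unadjusted p under 0.05.

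**Figure D2:**
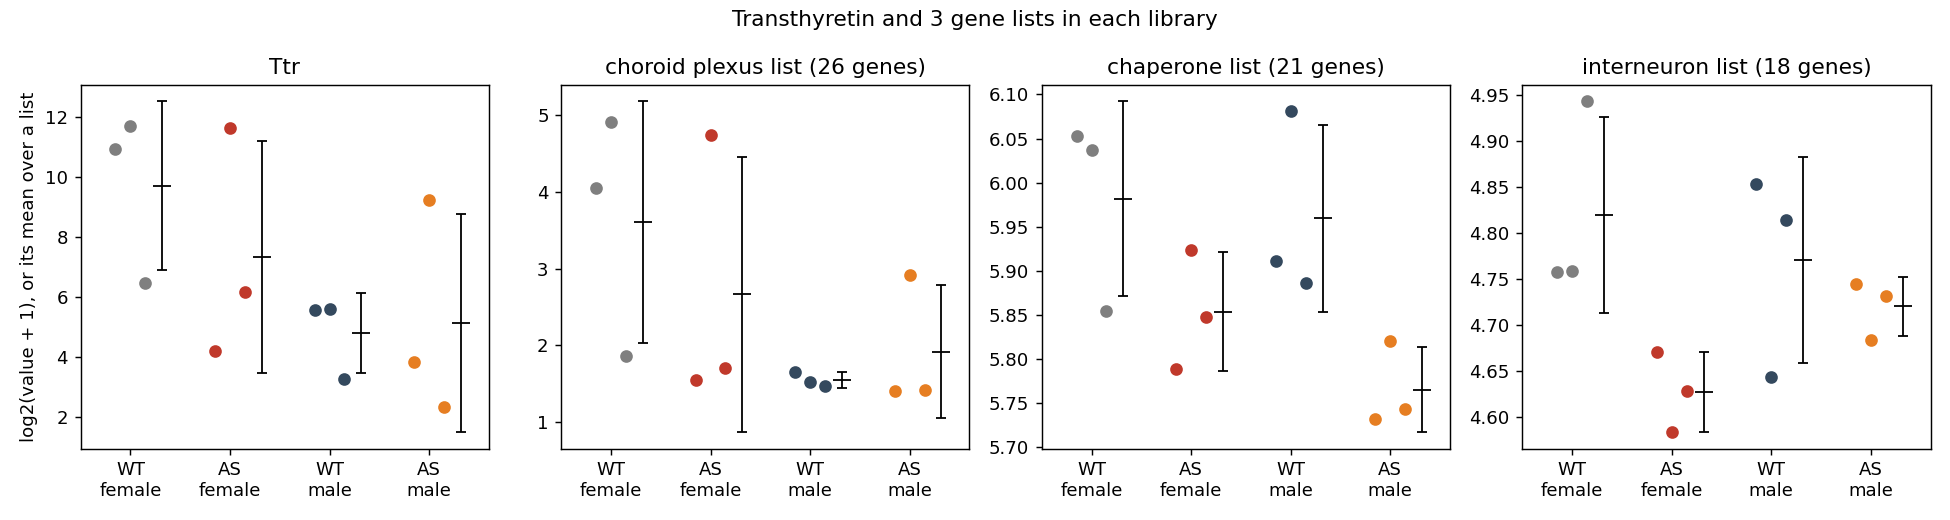
Ttr and the mean of the choroid plexus, chaperone and interneuron lists as log2(abundance + 1) in each library (points), with the group mean and SD (bars, n = 3). The vertical axes differ and do not start at 0. The choroid plexus mean reaches 4.91 in WT female replicate 2, while chaperone means of the AS groups lie below those of the WT groups.

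**Figure D3:**
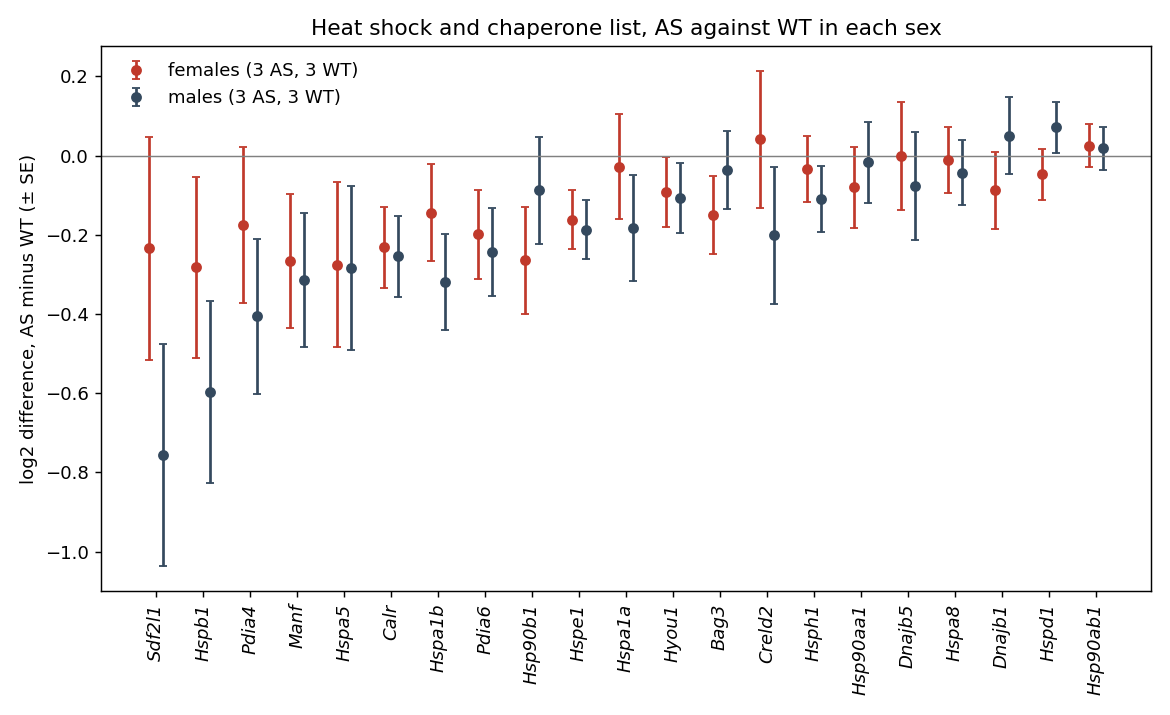
Log2 difference of AS minus WT for the 21 heat shock and chaperone genes in females and in males (points), with the SE of the model (bars, 3 mice per group). In the mean over both sexes 19 of 21 genes lie below 0.

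**Figure D4:**
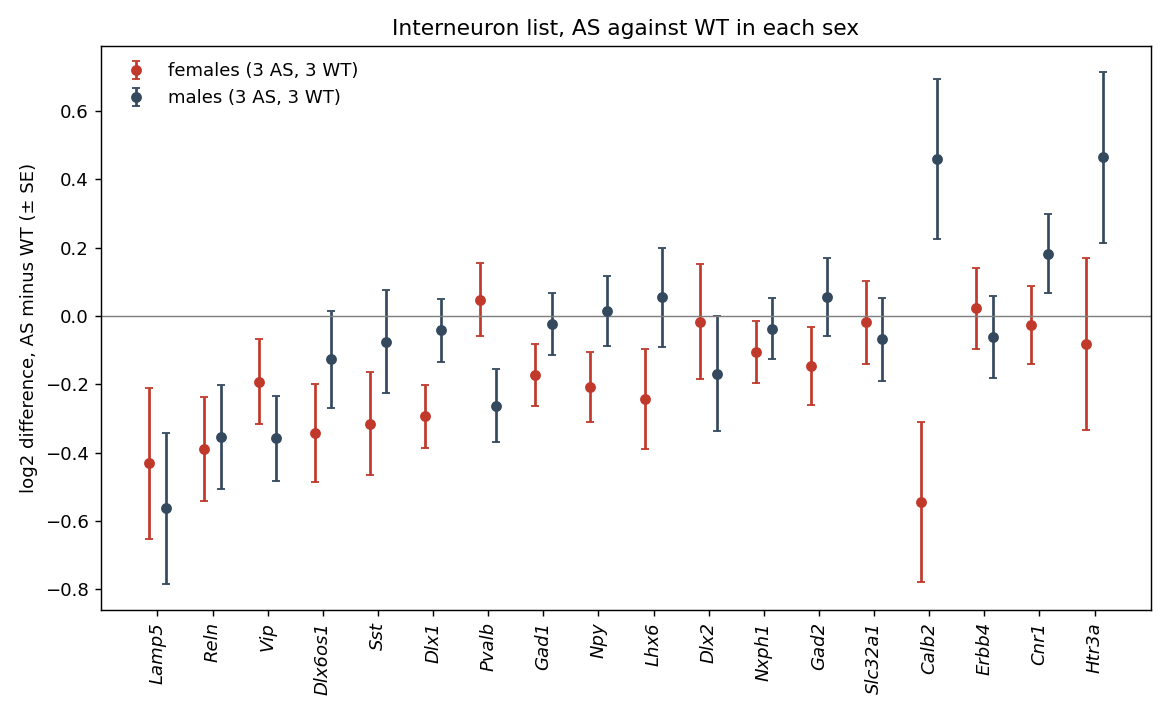
Log2 difference of AS minus WT for the 18 interneuron genes in females and in males (points), with the SE of the model (bars, 3 mice per group). In females 16 of 18 genes lie below 0.

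Interferon-stimulated genes and oligodendrocyte genes also passed over both sexes, and each rested on several libraries. Interferon-stimulated genes were higher in 13 of 14 cases, by a mean of 0.23 (adjusted p = 0.0238, and adjusted p = 0.859 with an estimated correlation). This list no longer passed without WT female replicates 1 or 3, AS female replicate 2, WT male replicates 1 or 2 or AS male replicate 2 (up to 0.784), and without the 4 libraries highest in choroid plexus genes (0.822). Oligodendrocyte genes were higher in 18 of 19 cases, by a mean of 0.12 (adjusted p = 0.0486, and adjusted p = 0.859 with an estimated correlation). The call ended without WT female replicates 1 or 3, AS female replicate 3, WT male replicates 1 or 3 or AS male replicates 2 or 3 (up to 0.602). With a mean abundance of at least 5 neither passed (0.346 and 0.0774), nor did the interferon list with library quality weights (0.489). Lists of sensory genes did not pass over both sexes: olfactory transduction had 7 of 11 tested genes higher (adjusted p = 0.314), hearing and mechanosensation had 9 of 10 lower (adjusted p = 0.493), and phototransduction and lens had 5 of 7 higher (adjusted p = 0.845). Glutamate receptor genes (14 of 22 higher, adjusted p = 0.731), GABA receptor subunits (11 of 14 higher, adjusted p = 0.509), markers of CA1 and subiculum (9 of 11 lower, adjusted p = 0.266) and markers of dentate granule cells (8 of 15 higher, adjusted p = 0.914) did not pass.

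No single gene passed over both sexes with limma (0 higher, 0 lower), while 741 had an unadjusted p under 0.05, against 693 expected by chance (615 without AS female replicate 1, 1170 with library quality weights). Of 100 relabellings of genotype, 26 gave at least 741 such genes, and those other than the real one ran from 258 to 1696. The smallest adjusted p, 0.297, was shared by Tmsb15b2 (chromosome X, 136955265 to 136975497, minus strand), at 0.59 ± 0.09, a ratio of 1.51 in abundance + 1, and by Lynx1 (chromosome 15, 74747852 to 74753046, minus strand), at -0.41 ± 0.06. Without WT male replicate 2, Tmsb15b2 passed at 0.66 (adjusted p = 0.0466) beside Snora21, and without WT female replicate 1 Snord15b passed (adjusted p = 0.0420). The next genes did not pass (adjusted p = 0.429 for Tmem254c and 0.593 for the rest). They were Tmem254c at 0.85 ± 0.15, Sh3gl3 at 0.29 ± 0.06 and Xrcc6 at 0.30 ± 0.06 on the higher side, with 1 intronic RNA. On the lower side they were Dlx1as at -0.28 ± 0.06, Aifm3 at -0.30 ± 0.06, the C-type lectin gene Cd302 at -0.33 ± 0.07 and Hist3h2a at -0.52 ± 0.11. Dlx1as is annotated opposite Dlx1, and the strand setting of the counting is not given, so the values of these genes may share reads, as may those of Tmem254c and its near copies.

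Whether the AS effect differs between the sexes was tested as the interaction, where positive values mean a higher AS minus WT difference in males. Postsynaptic density and CaMKII genes had 17 of 20 members lower, with a median of -0.11 (adjusted p = 0.0278, and adjusted p = 0.868 with an estimated correlation). The scaffold genes Shank1 and Shank2 were at -0.31 ± 0.11 and -0.31 ± 0.11. This call ended without WT female replicates 2 or 3, AS female replicate 3, WT male replicate 2 or AS male replicates 1 or 2 (up to 0.218), and with the choroid plexus mean as a covariate (0.0571) or library quality weights (0.0995). Axon initial segment and sodium pump genes had 11 of 17 lower, with a median of -0.08 (adjusted p = 0.0227, and adjusted p = 0.795 with an estimated correlation). Among them were Sptbn4, which encodes a spectrin of the initial segment, at -0.40 ± 0.13, the sodium channel gene Scn8a at -0.30 ± 0.10 and the potassium channel gene Kcnq3 at -0.42 ± 0.16, and the call ended without WT female replicates 2 or 3, AS female replicate 2, WT male replicate 3 or AS male replicate 1 (up to 0.111). Ribosomal protein genes had 42 of 58 higher, with a median of 0.06 (adjusted p = 0.0227, and adjusted p = 0.868 with an estimated correlation), and Rpl10a at 0.37 ± 0.13, Rpl5 at 0.37 ± 0.13 and Rpl23 at 0.22 ± 0.10. That call ended without WT female replicates 2 or 3, AS female replicates 2 or 3, WT male replicate 3 or AS male replicates 1 or 3 (up to 0.646). Proteasome genes had 26 of 31 higher, with a median of 0.06 (adjusted p = 0.0227, and adjusted p = 0.868 with an estimated correlation). This list lost its call without WT female replicate 3, AS female replicate 3, WT male replicate 3 or AS male replicate 3 (up to 0.185). All 26 choroid plexus genes were higher, with a median of 1.23 (adjusted p = 8.93e-05, and adjusted p = 0.868 with an estimated correlation). This call ended without WT female replicate 2 or AS female replicate 1 (up to 0.0866) and without the 4 libraries highest in these genes (0.601).

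No single gene passed the interaction with limma (0 higher, 0 lower), while 522 had an unadjusted p under 0.05, against 693 expected by chance (744 without AS female replicate 2, 839 without the 4 libraries highest in choroid plexus genes). The genes with the smallest p had an adjusted p of 0.987 each. On the higher side were Comtd1 at 0.82 ± 0.18, Hscb at 0.65 ± 0.14, Gtf3c6, which encodes a subunit of a transcription factor of RNA polymerase III, at 0.35 ± 0.08, the co-chaperone gene Dnajc12 at 0.59 ± 0.14 and 1 pseudogene. On the lower side were Get4 at -0.40 ± 0.08, Sorl1 at -0.39 ± 0.08, the long noncoding RNA Miat at -0.54 ± 0.12 and 2 antisense RNAs. On leaving out 1 library, 1 small noncoding RNA passed in each of 3 cases: Snord15b without WT female replicate 1, Gm24409 without WT female replicate 3 and Snora21 without WT male replicate 2. Across the 13858 genes, the AS effects in females and in males, which come from different mice, had a Pearson's r of -0.02 and a Spearman's rho of 0.03, and genes are not independent replicates. Of 252 genes with an unadjusted p under 0.01 in 1 sex, 60.3% had the same sign in the other, a share that ran from 52.9% without AS female replicate 2 to 65.4% without AS male replicate 2. At an unadjusted p under 0.05 in both sexes, 25 genes were higher in both (6.65 expected), 23 lower in both (7.42 expected) and 23 opposite (14.1 expected). Both effects use the same estimate of each gene's spread, which can raise such overlaps in either direction. It does not by itself explain the larger excess of genes that moved the same way. These overlaps were not compared with relabellings, so their cause was not tested.

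Between WT males and WT females, the Y-linked genes separated the sexes. Eif2s3y was higher in males by 5.30 ± 0.17 (adjusted p = 2.77e-08), Ddx3y by 3.53 ± 0.28 (adjusted p = 0.000254), Uty by 2.32 ± 0.22 (adjusted p = 0.00114) and Kdm5d by 2.71 ± 0.29 (adjusted p = 0.00337), each in 3 of 3 male libraries and against values at background in females. They were the 4 genes called higher, and 0 genes were called lower, with 1067 genes at an unadjusted p under 0.05 (693 expected, and 655 with the choroid plexus mean as a covariate). The Y-linked list passed (adjusted p = 9.44e-22, and adjusted p = 0.00178 with an estimated correlation), with 4 of 4 members also passing adjusted over the list alone. X-inactivation and escape genes were lower in 7 of 8 cases (adjusted p = 0.000104, and adjusted p = 0.455 with an estimated correlation), 4 of them passing adjusted over the list alone. Xist was at -4.05 ± 1.19, Kdm5c, a histone demethylase gene, at -0.46 ± 0.10, Ddx3x at -0.41 ± 0.11 and Eif2s3x at -0.48 ± 0.15. Without WT female replicate 1, 8 genes were called, among them Xist at -6.06, Kdm5c at -0.59 and Eif2s3x at -0.71. Kdm5d no longer passed with log2(abundance + 0.1) (adjusted p = 0.0842), with the choroid plexus mean as a covariate (0.0737) or without the 4 libraries highest in choroid plexus genes (0.0992), and Uty did not in the last of these (0.0657).

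Choroid plexus and ependyma genes were lower in WT males than in WT females. All 26 choroid plexus genes were lower, by a mean of -2.06 (adjusted p = 1.17e-16, and adjusted p = 0.455 with an estimated correlation), with Calml4 at -2.39 ± 0.85 and the claudin gene Cldn2 at -2.43 ± 0.87. All 11 ependyma genes were lower, by a mean of -0.62 (adjusted p = 1.35e-06, and adjusted p = 0.455 with an estimated correlation), with the cilium gene Rsph1 at -1.06 ± 0.24 and Foxj1, the regulator of motile cilia, at -0.64 ± 0.26. Rsph1 was the 1 ependyma gene that passed adjusted over the list alone, and without the 4 libraries highest in choroid plexus genes the ependyma list did not pass (0.104), while the choroid plexus list did (0.00312), with a median of -0.22 in place of -1.94. WT female replicates 1 and 2 were both high in choroid plexus genes and no WT male was. The WT male mean of 1.55 lay close to 1.47, the highest Y-linked value in a female library, which was read as background. Proteasome genes were lower in 26 of 31 cases, by a mean of -0.06 (adjusted p = 0.00302, and adjusted p = 0.455 with an estimated correlation). Their call did not hold without WT male replicate 3 (0.0798). Circadian clock genes were higher in 12 of 17 cases by a mean of 0.13 (adjusted p = 0.0248, and adjusted p = 0.455 with an estimated correlation), with Ciart at 0.43 ± 0.14 and Per3 at 0.46 ± 0.17. That call ended without WT female replicate 1 or WT male replicate 2 (up to 0.193), with the choroid plexus mean as a covariate (0.0770) and without the 4 libraries highest in choroid plexus genes (0.119). Axon initial segment genes were higher in 13 of 17 cases, with Sptbn4 at 0.37 ± 0.09 (adjusted p = 0.0413, and adjusted p = 0.455 with an estimated correlation). This list no longer passed without WT female replicates 2 or 3, AS female replicate 2 or WT male replicates 2 or 3 (up to 0.295). Postsynaptic density and CaMKII genes were higher in 14 of 20 cases, with Camk2g at 0.23 ± 0.08 (adjusted p = 0.0445, and adjusted p = 0.736 with an estimated correlation). Their call ended without WT female replicates 2 or 3, AS female replicates 1 or 2, WT male replicates 2 or 3 or AS male replicate 1 (up to 0.503), and with the covariate (0.175). With library quality weights the clock, axon initial segment and postsynaptic calls ended (0.0553, 0.0704 and 0.0925), as did the latter pair with a mean abundance of at least 5 (0.0543 and 0.0552).

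The other 4 lists that passed between WT males and WT females moved by less or rested on few libraries. Blood genes were higher in 7 of 7 cases (mean 0.63, adjusted p = 0.0328, and adjusted p = 0.736 with an estimated correlation), with the neutrophil gene S100a9 at 1.23 ± 0.46. That list lost its call without WT female replicate 2 or WT male replicates 1 or 2 (up to 0.227) and without the 4 libraries highest in choroid plexus genes (0.267). Mitochondrially encoded genes were lower in 13 of 13 cases (mean -0.13, adjusted p = 0.0143, and adjusted p = 0.839 with an estimated correlation). The call ended without WT female replicate 2 (0.137), with the choroid plexus mean as a covariate (0.616) and with quantile normalization again (0.885). The last of these evens out the highest genes largely by design, so it does not test this call. Ribosomal protein genes were lower in 40 of 58 cases (mean -0.04, adjusted p = 0.0428, and adjusted p = 0.849 with an estimated correlation). This list lost its call without WT female replicates 2 or 3, AS female replicate 2 or WT male replicate 3 (up to 0.962). Nuclear genes of oxidative phosphorylation were lower in 46 of 69 cases (mean -0.03, adjusted p = 0.0413, and adjusted p = 0.849 with an estimated correlation). This call ended without WT female replicate 3, AS female replicate 2 or WT male replicate 3 (up to 0.962). The blood, ribosomal and oxidative phosphorylation calls also ended with a mean abundance of at least 5 (0.264, 0.0557 and 0.0552) and with library quality weights (0.0704, 0.0914 and 0.0925). Among single genes that did not pass, Ap4m1, which encodes an adaptor protein subunit, was at 0.44 ± 0.07 (adjusted p = 0.0773, and 0.0291 with library quality weights) and Stac3 at 1.17 ± 0.19 (adjusted p = 0.170). Miat was at 0.47 ± 0.09, Ypel4 at 0.34 ± 0.07 and Stk11ip at 0.47 ± 0.09 (it passed without WT male replicate 3, adjusted p = 0.0141), while Gtf3c6 was at -0.27 ± 0.06, Sccpdh at -0.28 ± 0.06 and Cort, which encodes the neuropeptide cortistatin, at -0.68 ± 0.16 (adjusted p from 0.325 to 0.522). Groups did not overlap for 14.7% of genes, against 10% by chance.

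Between AS males and AS females, the Y-linked genes and Sorl1 passed. Eif2s3y was higher in males by 5.24 ± 0.17 (adjusted p = 3.16e-08), Ddx3y by 3.55 ± 0.28 (adjusted p = 0.000244), Uty by 1.86 ± 0.22 (adjusted p = 0.0114) and Kdm5d by 2.39 ± 0.29 (adjusted p = 0.0121), each in 3 of 3 male libraries. Sorl1 (chromosome 9, 41964720 to 42124297, minus strand) was lower in males, at 5.38 ± 0.01 against 5.79 ± 0.09 (SD, n = 3), a difference of -0.41 ± 0.06 (adjusted p = 0.0357). Its difference stayed between -0.46 and -0.38 on leaving out 1 library, but it no longer passed when any library other than WT female replicate 1 or AS female replicate 2 was left out (up to 0.276), in a fit of only these 2 groups (0.530), with log2(abundance + 0.1) (0.0630) or without the 4 libraries highest in choroid plexus genes (0.196). These 4 higher and 1 lower genes stand beside 503 genes at an unadjusted p under 0.05 (693 expected, 884 without AS male replicate 2 and 1034 with library quality weights). The Y-linked list passed (adjusted p = 1.06e-28, and adjusted p = 0.000644 with an estimated correlation), with 4 of 4 members passing adjusted over the list alone. X-inactivation and escape genes were lower in 8 of 8 cases (adjusted p = 3.74e-11, and adjusted p = 0.0989 with an estimated correlation), 5 of them passing adjusted over the list alone, with Xist at -6.03 ± 1.19, Kdm5c at -0.49 ± 0.10, Eif2s3x at -0.59 ± 0.15 and Ddx3x at -0.33 ± 0.11. Without WT female replicate 1, which widens the spread used for these genes, 8 genes were called. Kdm5d no longer passed without AS female replicate 3 or AS male replicates 1, 2 or 3 (up to 0.132), and Uty without AS male replicates 2 or 3 (up to 0.132), so that 2 or 3 genes were called in these fits. With log2(abundance + 0.1), in a fit of only these 2 groups, or without the 4 libraries highest in choroid plexus genes, Uty (0.101 to 0.261) and Kdm5d (0.154 to 0.309) did not pass.

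Myelin, microglial and choroid plexus transcripts were lower in AS males than in AS females, in calls that each rested on few libraries. Oligodendrocyte genes were lower in 19 of 19 cases by a mean of -0.19 (adjusted p = 0.00151, and adjusted p = 0.798 with an estimated correlation), with the transferrin gene Trf at -0.47 ± 0.19, and the call ended without AS female replicate 3 or AS male replicate 1 (up to 0.470). Microglial genes were lower in 12 of 16 cases by a mean of -0.10 (adjusted p = 0.00256, and adjusted p = 0.798 with an estimated correlation), with the complement genes C1qb at -0.30 ± 0.12 and C1qa at -0.25 ± 0.11. Interferon-stimulated genes were lower in 14 of 14 cases by a mean of -0.36 (adjusted p = 0.00256, and adjusted p = 0.798 with an estimated correlation). The microglial and interferon calls ended without AS female replicate 2 or AS male replicate 1 (up to 0.392 and 0.212), with the choroid plexus mean as a covariate (0.106 and 0.272) and without the 4 libraries highest in those genes (0.462 and 0.922). Choroid plexus genes were lower in 26 of 26 cases by a mean of -0.75 (adjusted p = 0.000466, and adjusted p = 0.798 with an estimated correlation). Their call did not hold without AS female replicate 2 or AS male replicates 1 or 3 (up to 0.187), but held without the 4 libraries highest in these genes (0.0248), with a median of -0.11 in place of -0.70. Ependyma genes were lower in 10 of 11 cases by a mean of -0.27 (adjusted p = 0.00765, and adjusted p = 0.798 with an estimated correlation), and chaperone genes in 16 of 21 by a mean of -0.09 (adjusted p = 0.0444, and adjusted p = 0.798 with an estimated correlation). Both ended without AS female replicates 2 or 3 or AS male replicates 1 or 3 (up to 0.294 and 0.463) and with the covariate (0.187 and 0.283), and the chaperone call also without the 4 libraries (0.0953), with quantile normalization again (0.202) and with library quality weights (0.0524). Library quality weights also ended the interferon (0.0524) and microglial (0.121) calls, and a mean abundance of at least 5 the ependyma call (0.355). Mitochondrially encoded genes were lower in 13 of 13 cases by a mean of -0.12 (adjusted p = 0.00284, and adjusted p = 0.798 with an estimated correlation). This list no longer passed without AS female replicate 2 or AS male replicates 1 or 3 (up to 0.825), with the covariate (0.242) and with quantile normalization again (0.858). Repeated quantile normalization evens out the highest genes largely by design, so it does not test this call. Among single genes that did not pass, Eid2 was at 0.31 ± 0.07, the replication helicase gene Mcm7 at 0.42 ± 0.09, the RNA export gene Nxf1 at 0.33 ± 0.08 and the serotonin receptor gene Htr7 at 0.37 ± 0.09, with 1 pseudogene. On the lower side were Ppm1h at -0.37 ± 0.07, Get4 at -0.25 ± 0.05 and S100a5 at -0.78 ± 0.18 (adjusted p from 0.244 to 1.00 for these genes). Groups did not overlap for 8.47% of genes, against 10% by chance.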

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

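The comparisons with other splits of the libraries were planned, while the tests of why choroid plexus genes differ between libraries were chosen after the result was seen.

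For the interaction of genotype and sex, 5 gene lists passed camera with a preset correlation. That test sets the genes of a list against all other genes and does not show that their interaction differs from 0. The same 5 lists passed in the other direction between WT males and WT females, a contrast that uses the same WT libraries. The median log2 value was -0.082 for axon initial segment and sodium pump genes, -0.11 for postsynaptic density and CaMKII genes, 0.060 for cytosolic ribosomal protein genes, 0.063 for ubiquitin-proteasome subunits and 1.23 for choroid plexus genes. With an estimated correlation none passed (adjusted p from 0.795 to 0.868), and none passed with fry. Of 100 relabellings of genotype within each sex, 94 gave at least 5 lists, and the highest of the others gave 15, so chance cannot be excluded for the number of lists. For single genes the real count was 0, which all 100 relabellings must equal or exceed, so their number decides nothing. The highest of the others gave 50.

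Choroid plexus genes were high in WT female replicates 1 and 2, AS female replicate 2 and AS male replicate 2, so the size of their group differences depends on where these 4 libraries fall. Without them the medians kept their sign, at -0.089 (-0.95 with all 12) for AS against WT in females, 0.042 (1.23) for the interaction, -0.22 (-1.94) between WT sexes and -0.11 (-0.70) between AS sexes. Between AS sexes the sign turned without AS female replicate 2 alone (0.28). Choroid plexus tissue left on some of the dissected pieces is a candidate source, as a hypothesis: the 26 genes moved together within groups (correlation between genes of 0.958), Ttr reached 11.7, 2 of the 26 genes are on another list, and no sort would have removed such tissue. The rule set for this source also asked that, in each group with a high library, the list mean range over more than the WT difference of 2.06. The range was 3.04 in WT females and 3.18 in AS females but 1.51 in AS males, so that part was not met. A difference by sex stays open as well, because the list mean differed between 6 males and 6 females with an exact permutation p of 0.0649, with 0.1 among WT mice, the smallest that 3 against 3 allow, and 0.5 among AS mice. Sex and tissue carried along cannot be told apart for WT mice, since 2 of 3 WT females and no WT male were high. Without the 4 libraries the list still passed between WT sexes (adjusted p = 0.00312) and between AS sexes (0.0248), with means of 1.55 to 1.86 in the remaining females, of which 1 is WT, and 1.41 to 1.66 in the males. That fit sets 1 WT female against 3 WT males, and the preset correlation of 0.01 lies far below that of these genes, so it does not decide between tissue and sex, and both stay open. The remaining means also lie close to 1.47, the highest Y-linked value in a female library, which was read as background. For genotype within each sex, the list mean differed by -0.29 with an exact permutation p of 0.705 (adjusted 0.932), and this does not show that genotype has no part.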

How the results depend on the processing

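Alternatives that need counts (scaling factors, count models, count filters) were not run, because the table holds logs of normalized values. Quality weights, the robust prior, repeated quantile normalization, the choroid plexus covariate, the fit without 4 libraries and the added constant for Xist were chosen after seeing the data. Of 2678 values of named genes under alternatives, 2637 kept their direction and side of the threshold, 29 no longer passed, 12 newly passed and 0 reversed. Most named genes had not passed with all 12 libraries, many far from the threshold, so keeping their side of it says little. The 29 losses were all of Sorl1, Uty or Kdm5d. Leaving out a library of a group outside the contrast cannot change a difference, only its error. Of 939 values of lists that passed, 700 kept both, 226 no longer passed and 13 reversed. Depth is unknown, so what it limits cannot be given. Where no cause is named below, the cause was not tested.

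Leaving out the 4 libraries highest in choroid plexus genes leaves 1 WT female, assumed to vary like the other groups. The genes then called by genotype or for the interaction all had names of small noncoding RNAs or predicted genes. They moved by large steps, such as Snord15b at -3.89 and Gm23257 at 4.64 in females and Gm22270 at 4.26 in males. Between WT sexes the newly called genes were Xist, at -6.03, and RNAs of these kinds. List counts became 8 in males, 13 over both sexes and 10 for the interaction. Medians of interferon-stimulated genes were then 0.040 in females, with the test reversed, -0.0028 over both sexes and 0.0096 between AS sexes, and that of X-inactivation genes in females -0.048. Agreement in sign became 55.7%, and 55.3% with the choroid plexus covariate. With that covariate 10 lists passed over both sexes and 3 between AS sexes, and the median of mitochondrially encoded genes between WT sexes was 0.016. With a mean abundance of at least 5, which tests fewer genes, 2 genes passed between WT sexes and 3 between AS sexes, and 6 lists between WT sexes. With log2(abundance + 0.1), 2 genes passed between AS sexes, and Xist in WT female replicate 1 lay at -7.72 from the other females. In a fit of only the AS groups 3 genes passed. With quality weights 8 lists passed in males and 6 between WT sexes, and Ube3a in the interaction was -0.016. With quantile normalization again 5 lists passed in males, and the median of mitochondrially encoded genes was 0 between WT sexes and 0 between AS sexes. These genes, with group means from 12.6 to 12.8, are among the highest, where the deposited columns share no values. That step gives genes of equal rank equal values, so it removes such a difference largely by design and does not test it. With an estimated correlation, and with fry, 0 lists passed in females, males, both sexes and the interaction, and 1 (Y-linked genes) between the sexes of each genotype.

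On leaving out each library in turn, genes called ran from 0 to 1 in females, 0 to 1 in males, 0 to 2 over both sexes, 0 to 1 for the interaction, 4 to 8 between WT sexes and 2 to 8 between AS sexes. Lists ran from 7 to 16 in females, 2 to 8 in males, 5 to 11 over both sexes, 2 to 13 for the interaction, 7 to 13 between WT sexes and 3 to 13 between AS sexes. Agreement in sign ran from 52.9% to 65.4%. Ube3a ran from -0.19 to 0.078 in males, -0.064 to 0.20 for the interaction and -0.23 to 0.031 between AS sexes. List medians that reversed in some of these fits ran from -0.099 to 0.64 for interferon-stimulated genes in females, -0.043 to 0.36 over both sexes and -0.57 to 0.11 between AS sexes, -0.013 to 0.22 for X-inactivation genes in females, -0.060 to 0.025 for ribosomal protein genes between WT sexes and -1.23 to 0.28 for choroid plexus genes between AS sexes. Fewer libraries were then fitted.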

Other observations

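The planned work here is the comparison with other splits of the libraries and the fits without 1 library, while the tests of why Xist is low in WT female replicate 1 and of the neighbourhood of Ube3a, and the covariate and list-mean tests of the chaperone genes, were chosen after the results were seen.

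Several gene lists not described so far differed between groups of mice without passing. Immediate early genes, which neurons switch on with activity, were higher in 16 of 21 cases in AS females (mean 0.09, adjusted p = 0.596) and lower in 16 of 21 cases in AS males (mean -0.17, adjusted p = 0.234), and the interaction did not pass (adjusted p = 0.192). Markers of CA3 and mossy cells were higher in 11 of 12 cases in AS males (mean 0.11, adjusted p = 0.358) and lower in 8 of 12 cases in AS females (mean -0.09, adjusted p = 0.279), and the interaction did not pass (adjusted p = 0.161). Markers of cortex and amygdala were lower in AS mice over both sexes in 11 of 16 cases (mean -0.16, adjusted p = 0.0591). In list means over 6 males against 6 females, oligodendrocyte precursor genes were at -0.09 in males (exact permutation p = 0.0195, adjusted 0.164) and extracellular matrix and perineuronal net genes at -0.06 (exact permutation p = 0.0152, adjusted 0.159).

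In WT female replicate 1, Xist was 0.35 while it averaged 6.32 in the other females. A male mouse under a female label is ruled out by the Y-linked genes, whose mean of 0.676 lies below the lowest male mean of 3.86 and among the other females (0.237 to 0.926). A mixture of male and female RNA would need the shares of Xist and of Y-linked genes to add up to about 1, and they add up to 0.00284. Loss of the Xist value alone is argued against by 4 of 4 escape genes lying below all other females. These were the members of the list in which males and the other females did not overlap. Of all 7 tested members besides Xist 5 lay below, and Jpx and Ftx did not. A candidate explanation that remains, as a hypothesis, is a single X chromosome and no Y: on a scale from the male mean to the mean of the other females the median place of the escape genes was 0.126 (0.806 to 1.21 in other females), though Kdm5c at 0.390 lies in between.

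Chaperone genes were lower in AS mice over both sexes. Among 100 relabellings of genotype within each sex, only the real grouping, 1 of 100, gave a camera p as small for this list (6.16e-09 against 2.92e-07 for the next). The real grouping was always among those drawn, so 1 of 100 is the smallest share possible. Yet 66 of 100 had some list with a p as small (down to 4.88e-77). Chance is thus less likely for the list taken alone but not excluded, and it is not excluded for the smallest of 42 lists. The mean difference of its list mean had an exact permutation p of 0.015, or 0.525 adjusted over 42 lists, and the corresponding values were 0.045 and 0.63 for interneurons, 0.07 and 0.735 for glucocorticoid-responsive genes and 0.11 and 0.77 for proteasome subunits. Extracellular matrix genes, a list that did not pass, had 0.025 and 0.525. Choroid plexus tissue carried along is argued against as the whole cause by the mean difference with that covariate. It was -0.15 ± 0.03 against -0.16 ± 0.03 (SE over member genes, not over mice, adjusted p = 4.84e-08 by camera with the preset correlation). Over both sexes the choroid plexus mean itself differed by only -0.29 (exact permutation p = 0.705), which leaves the covariate little to remove. Among WT females, however, the chaperone mean was 6.05 and 6.04 in replicates 1 and 2, high in choroid plexus genes, and 5.85 in replicate 3. In AS females it was 5.92 in replicate 2, high in these genes, and 5.79 and 5.85 in the others. A part of such tissue in the female difference thus stays open. The library low in Xist is argued against as the whole cause by the mean of -0.14 without it (adjusted p = 1.17e-05 by camera with the preset correlation). Neither of these p bears on chance, since with an estimated correlation the list did not pass. A difference in handling of the tissue between genotypes was not tested and may remain, beside genotype itself.

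Whether genes near Ube3a on chromosome 7 changed with genotype, as a stretch of chromosome carried with the mutation might make them, was tested within 20 Mb. Of 174 genes 15 had an unadjusted p under 0.05 (8.62%, against 5.35% of all genes), 16 of 100 relabellings gave as many, and the highest of the others gave 20, so this was not decided. The rule for reading this test was set after its value was seen.

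For AS against WT over both sexes, 89 of 100 relabellings gave at least the real 6 lists (highest of the others 14), so chance cannot be excluded for their number. The real count of genes was 0, which all 100 must equal or exceed (highest of the others 59), so that comparison decides nothing. The correlation of the AS effects between the sexes was matched or exceeded in 54 of 100 relabellings for Pearson's r (real -0.02, highest of the others 0.208) and in 37 for Spearman's rho (real 0.03, highest of the others 0.245), so chance cannot be excluded there.

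The comparisons of 3 libraries against 3 have 10 splits, too few for a share under 0.05. In AS against WT females, 10 splits gave at least the real 0 genes (highest other 88) and 4 at least the real 10 lists (highest other 15). The split with 88 genes set WT female replicates 1 and 2 and AS female replicate 2, the females high in choroid plexus genes, against the rest, which points to a structure of the samples. In AS against WT males, 10 splits gave at least the real 0 genes (highest other 1) and 10 at least the real 3 lists (highest other 14). Between WT males and females, 1 split, the real one, gave 4 genes (highest other 2) and 2 gave at least the real 12 lists (highest other 14). Between AS males and females, 1 split, the real one, gave 5 genes (highest other 1) and 6 gave at least the real 9 lists (highest other 12).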
